A study of Vitis vinifera with 11 samples.

How the data were processed

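Small RNA libraries were made with the Illumina v1.5 small RNA protocol and sequenced single-end, with the oligoribonucleotide standards Std 2, Std 3 and Std 6 added to the RNA, per the labels' protocols. Plants were grown in 16 h days at 25 °C and 8 h nights at 20 °C. Each deposited file holds a unique sequence and its count per line. The counts are whole numbers of reads per sequence with no scaling, as tested on the files; how adapters were trimmed and reads were filtered is not stated in the labels. Total counts ranged from 17595372 to 27752943 reads in 10 files. The tendril node 3 file (5705575 reads) ended within a line and covered only the alphabetical start of its sequences, so its total is not a depth. It was used only in added comparisons restricted to the covered sequences. Reads of 18 to 28 nt without standards, the library size used for scaling, numbered 9250734 to 20744798 in complete libraries.

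The features tested were 37 microRNA or tasiRNA families and every other unique sequence of 20 to 24 nt. A family is the sum of reads of 20 to 22 nt that hold bases 3 to 18 of a listed mature sequence (52 in all), at an offset of 0 to 4, with at most 1 mismatch. Reads were assigned to the family with the fewest mismatches, and ties were left out. Near-identical families such as miR159 and miR319, or miR156 and miR157, can share reads. Sequences were not matched to a genome, so no coordinates are given and plant origin was not tested per sequence. The annotation ASM3070453v1 was used only to count annotated MIR genes per family name.

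The node 3 inflorescence libraries were summed into 1 sample after a check of duplicates. For each pair of libraries, a chi-square with 1 degree of freedom compared the reads of every sequence with at least 20 reads. This left 5 inflorescence samples against 2 tendril samples, where 6 against 3 had been intended. Counts were fitted with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr with a minimum count of 10, Benjamini-Hochberg at 0.05) in R 4.3.3 with limma 3.58.1. Node comparisons used the inflorescence samples with node as the group (2 residual degrees of freedom). The organ comparison added the tendrils of nodes 1 and 2 with node as a factor (3 degrees of freedom), and the slope comparison an interaction of organ with node as a number (3). In the organ fit the node 3 sample, with no tendril beside it, is fitted by its own node term. The organ folds and their errors therefore rest on nodes 1 and 2. The leaf comparison used the libraries labelled 06C021V0046 and those of L2 with genotype as a factor (4). Lists of families fixed beforehand were tested with fry, whose directional and mixed p-values were adjusted over 7 lists per comparison. fry tests whether a list's members move and does not compare the list with other features. TMM factors reached 1.93 in inflorescence node 2 replicate 2 and fell to 0.665 in tendril node 2.

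Shares of read lengths and reads per standard read were compared with two-sided exact permutation tests that enumerate all arrangements. Confidence intervals are Wilson intervals at 95%, and a count of 0 is bounded by a floor of 3 counts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

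Families were named when past the threshold, or as members of a fixed list with their values; miR156/miR157, miR172 and the standards were always named. Other sequences were named by the 4 largest rises and 4 largest falls among those past 0.05 with a mean of at least 20 CPM and the same direction in every matched pair, with 1 kept where several overlapped by 15 bases. That rule and the tests, lists and most alternatives were chosen before the data were examined. All 4 falls that the rule first picked lay on the circular contig described next. After their values were seen, sequences on or within 2 mismatches of it were left out of naming, and falls were also required to be 24 nt long and to have at least 10 inflorescence reads. This lowered the eligible sequences from 226 to 116. miR395, miR2111, miR535 and miR319 were named from their lists after their values were seen.

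Sequences of 20 to 24 nt with at least 5 reads in each complete L2 library and none in picovine libraries (11289, of which 7994 had at least 30 reads together) were assembled by overlaps of 14 bases between 15-mers, without a reference. The longest contig, of 382 bases, ended with the 14 bases it began with, which gives a circle of 368 bases. Reads were then matched to it exactly or with up to 2 mismatches.

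Replicate numbers name the same genotype at each node, per the labels, so they pair the libraries. Deviations of the replicates from their node means correlated across 27341 sequences with r = 0.506 between nodes 1 and 2, but r = −0.066 between nodes 1 and 3 and 0.024 between nodes 2 and 3, where the node 3 libraries are near duplicates. These correlations are across sequences, which are not independent replicates. Over the families r was 0.802, 0.353 and 0.277. The fit without the block is the main one, and the blocked counts stand beside it where they differ.

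Alternatives were DESeq2 1.42.0 (size factors and Wald test), scaling by the standards, no filter on low counts beyond a total of 20 reads, all sequences of 18 to 28 nt, reads identical to listed sequences, the replicate block, genotype as a factor, each genotype alone, each library left out in turn, and settings for the truncated, duplicate and contig sequences.

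The fits were tested on simulated counts with the real means and library sizes and 200 changed features, 100 by 4-fold and 100 by 16-fold. With the spread as estimated from the libraries, the 16-fold changes were recovered at 0% for node 3 against node 1 (238913 features), 0% for inflorescence against tendril (164159), 0% for the slope (164159) and 20% for leaf (141479), and the 4-fold changes at 0% in each. At 0.1 of that spread, recovery of 4-fold and 16-fold changes was 5% and 56% for node 3 against node 1, 28% and 84% for inflorescence against tendril, 1% and 20% for the slope, and 69% and 100% for leaf. Between 0 and 4 unchanged features were called. A count of 0 at the estimated spread therefore says little about whether changes are there. The simulated setting differs from the data, since only 200 features were changed and each had the spread typical of its level. In the real libraries the inflorescence against tendril fit called 7567 features, so its simulated recovery of 0% does not describe that fit.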

Results

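Small RNAs were sequenced from organs at nodes 1, 2 and 3 from the shoot apex of grapevine. Inflorescences came from 2 picovine genotypes, 06C021V0046 (replicate 1) and 06C008V0003 (replicate 2), tendrils from the control line Pinot Meunier L2 with 1 library per node, and leaves were pooled into 1 library for picovine 06C021V0046 and 1 for L2. The 10 complete files held between 17595372 and 27752943 reads. The tendril node 3 file held 5705575 reads and stopped in the middle of a line, in alphabetical order of sequence, so it covered only sequences that begin before CAGAGTTCAATC and stayed out of the main comparisons. The paired node 3 inflorescence libraries were near duplicates, with a median chi-square per sequence of 0.998 against 5.40 for the node 1 pair and 18.7 for the node 2 pair (sampling noise alone gives a median of 0.455). Nodes 1 and 2 of the same genotype lay nearer, at 1.47 in 06C021V0046 inflorescences and 2.31 in tendrils. Over sequences with at least 200 reads the node 3 pair had 1.37, against 12.8 and 22.5 for those pairs. The node 3 libraries were therefore summed and counted as 1 sample, which leaves 5 inflorescence samples. Levels below are CPM, counts scaled to library size and by TMM, with the standard deviation (SD) between samples. Intervals and floors cover counting error only.

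Small RNAs of 24 nt, the class that plants make mainly in RNA-directed DNA methylation, were the most abundant length in every complete library. They made up 45.2% ± 7.16 (SD, n = 5) of reads of 18 to 28 nt in inflorescences and 34.5% ± 3.41 (SD, n = 2) in tendrils. Within inflorescences the share was 35.9% and 47.4% at node 1, 43.1% and 44.0% at node 2, and 55.8% and 55.3% in the libraries of node 3. The leaf libraries had 45.6% (95% Wilson interval 45.6 to 45.7) in picovine and 41.1% (41.1 to 41.2) in L2. Reads of 21 nt, the usual microRNA length, made up 14.1% ± 2.35 (SD, n = 5) in inflorescences, 17.5% ± 2.05 (SD, n = 2) in tendrils, 20.7% (20.7 to 20.7) in the picovine leaf and 16.2% (16.2 to 16.3) in the L2 leaf. Neither difference between inflorescence and tendril passed the two-sided exact permutation test (24 nt p = 0.143, 21 nt p = 0.190, with 21 arrangements and a smallest possible p of 0.0476). A single 20 nt class made up 25.2% and 21.96% of reads in inflorescence node 1 and node 2 replicate 1, where a fragment from the start of the 18S ribosomal RNA held 21.8% and 19.6% of reads. With that fragment left out of the total, the 24 nt difference grew from 10.7 to 12.7 percentage points, with an exact permutation p of 0.0476, the smallest that the design can give. The 21 nt difference, −3.36 points, was −3.07 then (exact permutation p = 0.429), and it was −5.77 over reads of 20 to 24 nt and −2.77 over unique sequences, each with an exact permutation p of 0.0476.

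**Figure D1:**
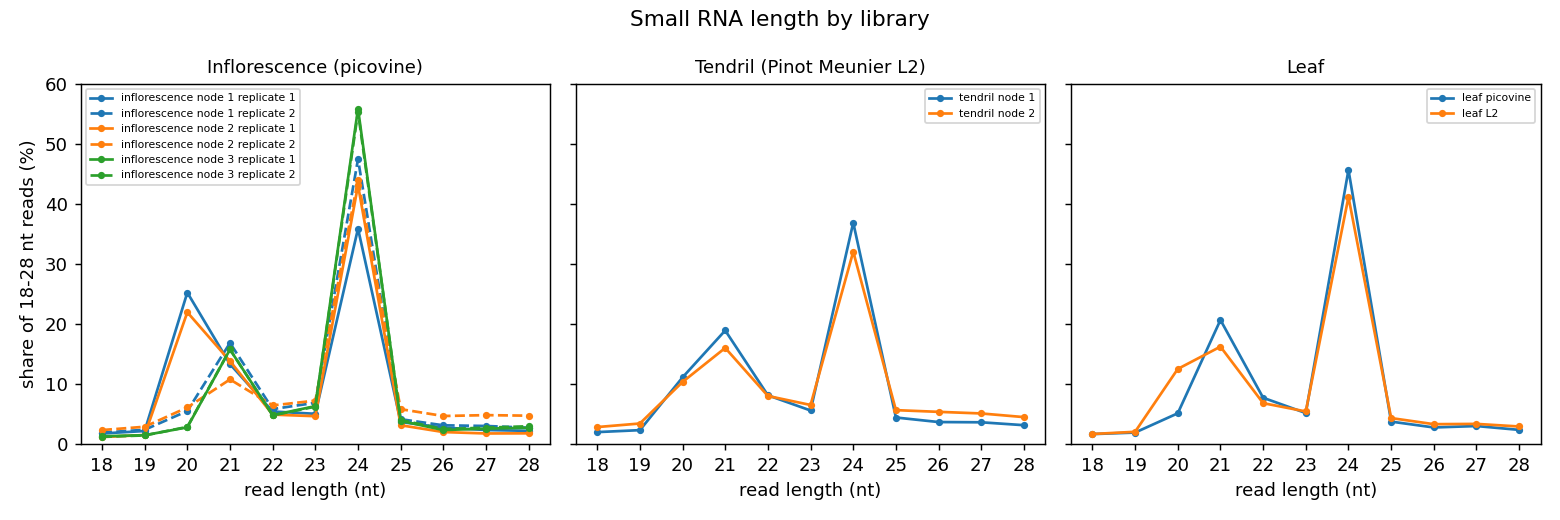
Share of reads (percent of 18 to 28 nt reads, vertical axis) at each read length (nt, horizontal axis) for the 10 complete libraries, with 1 line per library (dashed for replicate 2). The 24 nt peak lies between 35.9% and 55.8% in inflorescence libraries, at 36.9% and 32.04% in tendrils, and at 45.6% and 41.1% in leaves.

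The first question was how small RNAs change as an inflorescence develops from node 1 to node 3. Among the phase and floral timing families, miR172, which represses AP2-like genes, had 649 ± 670 CPM (SD, n = 2) at node 1, 202 ± 274 CPM at node 2 and 17.9 CPM at node 3. From node 1 to node 2 it went from 1123 to 395 CPM in genotype 06C021V0046 and from 176 to 7.99 CPM in 06C008V0003. The node 2 library of 06C008V0003 has few distinct sequences, and 33 of 37 families were lower in it than at node 1. The miR156/miR157 family, which represses SPL genes, had 156 ± 140 CPM at node 1, 471 ± 418 CPM at node 2 (SD, n = 2 each) and 270 CPM at node 3. Of the nutrient and copper families, miR395 had 49.9 ± 21.2, 31.1 ± 18.5 and 306 CPM at nodes 1, 2 and 3, and miR2111 had 3.46 ± 1.56, 7.93 ± 1.11 and 63.1 CPM. The 8 families of that list did not move together: from node 1 to node 3, 4 had higher and 4 lower folds. Among the lower were miR397 (log2 −3.28) and miR169 (−3.14). The miR3627-like family had 53.8 ± 47.6, 43.1 ± 58.1 and 1.19 CPM, with 20.1 and 2.07 CPM at nodes 1 and 2 in genotype 06C008V0003. None of these differences passed the test, and node 3, counted as 1 sample, has no spread of its own. The fitted log2 folds from node 1 to node 3 were −5.12 (SE 2.89) for miR172, 0.86 (SE 2.11) for miR156/miR157, 4.24 (SE 2.04) for miR2111, 2.67 (SE 2.02) for miR395 and −5.42 (SE 2.78) for miR3627-like, each with an adjusted p of 0.995 in edgeR's quasi-likelihood test. The node 3 sample is in doubt as to genotype, while node 1 is a mean over both. With the replicate block and without the node 3 library labelled 06C021V0046, the folds were −2.82 for miR172, 1.93 for miR156/miR157, 4.41 for miR2111, 2.74 for miR395 and −3.66 for miR3627-like, and none passed. The fall of miR172 was nearly absent in reads identical to a listed mature sequence, with a log2 fold of −0.47 from node 1 to node 3 and −0.50 from node 1 to node 2, against −1.79 for node 2 in the whole family. In the most abundant miR172 sequence, which held 46.5% of the family's reads, the folds were −5.68 and −1.91, and neither passed.

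None of the 37 families and none of the other sequences passed an adjusted p of 0.05 in the 3 node comparisons by edgeR (0 of 238913 features in each). At an unadjusted p under 0.05 there were 2374 features for node 2 against node 1, 7203 for node 3 against node 1 and 4922 for node 3 against node 2. Each is less than a share of 0.05 of the features, the share that no change at all would give, so these counts are no sign of change. DESeq2's Wald test called 37, 26 and 30. With the genotype as a replicate block and the libraries as labelled, edgeR called 1, 2215 and 0 features. The 2215 comprised 197 higher and 2018 lower at node 3, miR3627-like among the lower (log2 −5.25, SE 1.54, adjusted p = 0.0490). This fit rests on the near-duplicate node 3 libraries, and without the node 3 library labelled 06C021V0046 it called 1 feature. No list of families passed fry's test in these comparisons, in either form. The lists were phase and floral timing, auxin signalling, meristem and organ patterning, nutrient and copper, small RNA machinery, phasiRNA triggers, and grape or lineage restricted. With TMM scaling, members lay mostly below node 1 at node 2, with negative folds for 5 of 5 auxin families, 3 of 3 machinery families, 6 of 6 phasiRNA triggers and 7 of 8 lineage-restricted families, and no member passed, adjusted over all features or adjusted over the list alone. This is not particular to these lists: by CPM, of all 37 families, 27 were lower at node 2 in 06C021V0046 and 33 in 06C008V0003.

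**Figure D2:**
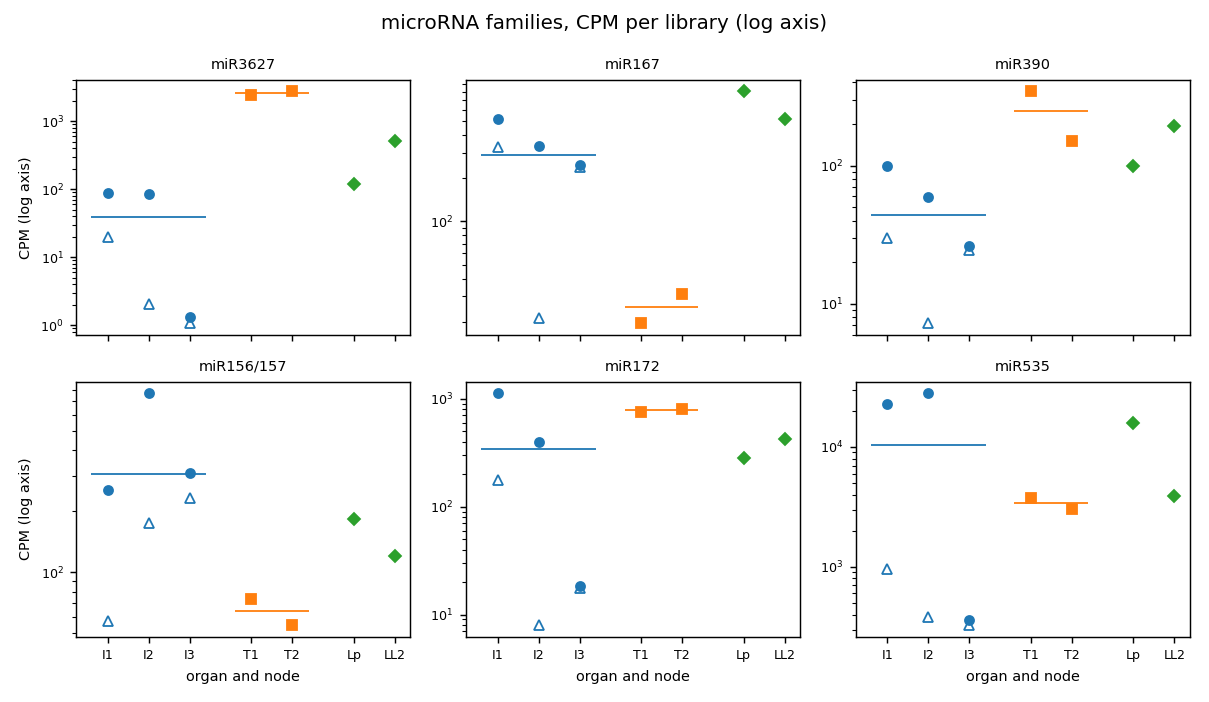
CPM per library (log axis) of 6 microRNA families in inflorescence nodes 1 to 3 (I1 to I3, filled circles replicate 1, open triangles replicate 2), tendril nodes 1 and 2 (T1, T2, squares), leaf of picovine (Lp) and leaf of L2 (LL2, diamonds). Horizontal lines are the means of 5 inflorescence and 2 tendril samples. The miR3627-like family averages 39.0 CPM in inflorescences and 2580 CPM in tendrils.

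The second question was which small RNAs distinguish inflorescences from tendrils, organs that form at the same nodes. Folds of the main fit rest on nodes 1 and 2, where both organs were fitted, while means with n = 5 include node 3. The miR3627-like family was the only family that passed, with 39.0 ± 43.4 CPM (SD, n = 5) in inflorescences and 2580 ± 210 CPM (SD, n = 2) in tendrils (log2 −5.70, SE 1.36, adjusted p = 0.0101 by edgeR, lower in 6 of 6 inflorescence libraries). A 22 nt sequence, TCTGTCGCAGGAGAGATGATGC, held 98.2% of its reads. It is not identical to the listed mature sequence, and was assigned by the rule of at most 1 mismatch over bases 3 to 18, which leaves the ends unchecked. Its level was 118 CPM in the picovine leaf and 517 CPM in the L2 leaf. The call was lost without tendril node 1 (log2 −6.11, adjusted p = 0.556) and without tendril node 2 (−5.44, 0.861), where the fold stayed about as large and its SE grew to 2.29. It was also lost with spike-in scaling (−3.16, 0.328) and with genotype as a factor (−3.42, 1.0), where the fold shrank. Among the auxin families, miR167, which targets auxin response factor genes, had 289 ± 179 CPM in inflorescences (SD, n = 5) and 25.4 ± 8.18 CPM in tendrils (SD, n = 2), with a log2 fold of 3.41 (SE 1.53) and an adjusted p of 0.1999. It passed without inflorescence node 2 replicate 2, a library with few distinct sequences (log2 4.09, adjusted p = 0.0165), and with only the libraries labelled 06C021V0046 (4.14, 8.83e-05), but not with only those labelled 06C008V0003 (2.02, 0.560). The fits of 1 genotype set 2 inflorescence libraries against 2 tendrils and left 1 residual degree of freedom. The miR390 family, which directs TAS3 cleavage, had 44.1 ± 35.7 and 248 ± 137 CPM, and the TAS3-derived tasiARF had 12.6 ± 8.46 and 41.0 ± 3.42 CPM in inflorescences and tendrils. Their log2 folds were −2.24 (SE 1.17) and −1.68 (SE 1.20), did not pass, and turned positive with spike-in scaling (0.32 and 0.83). That scaling raised the median fold of all features, so the turn is not particular to these families. With tendril node 3 in its covered range, miR390 passed (log2 −2.68, SE 0.83, adjusted p = 0.0233).

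By list, the auxin signalling families passed as a set in fry's mixed form, which disregards direction (mixed adjusted p = 0.00177). They did not pass its test of 1 common direction (fry adjusted p = 0.718). There were 1 positive and 4 negative folds, and no member was past 0.05, so no change is shown for a single family. The lineage-restricted list (mixed adjusted p = 0.00324) and the phasiRNA triggers (mixed adjusted p = 0.0494) each had miR3627-like as the member that passed, adjusted over all features and adjusted over the list alone. All 6 triggers had negative folds with TMM scaling, but the test of 1 common direction did not pass (adjusted p = 0.316). With spike-in scaling no list passed. In the phase and floral timing list, miR156/miR157 had 305 ± 272 CPM in inflorescences and 64.4 ± 13.6 CPM in tendrils (log2 2.06, SE 1.40, adjusted p = 0.390). It passed with only the libraries labelled 06C021V0046 (log2 2.86, adjusted p = 0.00416) and not with only those labelled 06C008V0003 (0.92, 0.765), in fits with 1 residual degree of freedom each. For miR172 the levels were 344 ± 463 and 784 ± 37.1 CPM (log2 −1.18, SE 1.34, adjusted p = 0.618), a fold that turned to 1.26 with spike-in scaling and to 1.39 in its most abundant sequence (46.5% of its reads), and was −4.39, past the threshold (adjusted p = 0.0308), in reads identical to a listed mature sequence. The turn of miR172 with spike-in scaling goes with the rise of the median fold of all features under it. The machinery, nutrient and patterning lists did not pass in either form of the test.

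Of 164159 features tested, edgeR called 1304 higher and 6263 lower in inflorescences than in tendrils. This imbalance depends on the test, since DESeq2's Wald test called 5466 higher and 5731 lower. Sequences of 24 nt, 117465 of the features tested, made up 1169 of the higher ones and 3321 of the lower ones. Sequences of 21 nt, 21566 of those tested, made up 58 and 1808. Among the 4 named sequences that rose, all of 24 nt, AACAGACTGAGAAGAAAAGGCAGC had a mean of 144 CPM in inflorescences and no read in tendril nodes 1 and 2, at least 1098-fold higher than the floor of 3 counts over both tendril libraries. TAAAAGATTAAGAAGACTAGACGC had 83.3 CPM (at least 634-fold), ATACAAGGTCTTCGAGGCAAGCGG had 97.7 CPM (at least 744-fold) and CGAAGGAAAGGACCGTAGAAGACC had 81.5 CPM (at least 620-fold). Single libraries weigh heavily in these means and bounds: TAAAAGATTAAGAAGACTAGACGC had 334 CPM in inflorescence node 2 replicate 2 and 1.70 to 39.9 CPM in the others, and ATACAAGGTCTTCGAGGCAAGCGG had 318 CPM in node 2 replicate 1 and 0.741 to 79.7 CPM in the others. Their adjusted p in edgeR lay between 0.00148 and 0.00421, and none of them exceeded 0.216 CPM in a leaf. The named sequences that fell were AATAGTAATCATGAATAGTAGACC (0.114 CPM in inflorescences, 695 CPM in tendrils), ATCTGTCGGAGAAGCAAGTCGGAG (0.476 and 940), ATTGACTTCTGAAAAGCTAAAAGC (0.169 and 608) and ATGAAGATCAATGAGTTCTGAACG (0.180 and 574). All 4 were also abundant in the L2 leaf, at 576 to 1579 CPM, and stayed at or below 0.540 CPM in the picovine leaf, with adjusted p between 0.000140 and 0.000159 in edgeR. All 8 lost their call with spike-in scaling, where the log2 folds stayed large (12.5 to 14.4 for the rises against 13.1 to 13.9, and −9.34 to −10.5 for the falls against −11.7 to −12.2) and the SE grew. All 8 also lost it with genotype as a factor, where the falls shrank to between −2.94 and −0.58, or turned to 0.59 for ATCTGTCGGAGAAGCAAGTCGGAG, while AACAGACTGAGAAGAAAAGGCAGC (13.6, SE 3.86) and CGAAGGAAAGGACCGTAGAAGACC (16.4, SE 4.99) stayed large and the other rises could not be estimated. The 4 that rose also lost it without either tendril library (adjusted p 0.247 to 0.808), and ATTGACTTCTGAAAAGCTAAAAGC and ATGAAGATCAATGAGTTCTGAACG lost it without tendril node 2 (0.0527 and 0.0544).

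Organ and genotype coincide in this design, since inflorescences are picovine and tendrils are L2. For the features lower in inflorescences, the L2 leaf exceeded the picovine leaf by a median of 88.5% of the median organ fold (log2), and 93.7% of them differed at least 2-fold between the leaves in the same direction. The features higher in inflorescences were nearly absent from leaves: 94.6% had a picovine leaf level under 10% of their inflorescence mean. A set of sequences that assemble into a circle of 368 bases held 1.55% to 3.12% of reads in tendril nodes 1 and 2 and 1.83% in the L2 leaf, all with up to 2 mismatches, against 1 read in all picovine inflorescences and 10 in the picovine leaf. It accounted for 1606 of the 6263 lower features (25.6%), or 1248 (19.9%) by exact matches. With genotype as a factor, estimated through the leaves, edgeR called 0 features (4518 at an unadjusted p under 0.05). That fit has no node term, keeps the node 3 inflorescence libraries apart as labelled, and sets each organ against 1 leaf library of its genotype. 06C008V0003 has no leaf library, so its libraries do not enter the fold. A count of 0 there does not show that the organs are alike. The counts that follow are without genotype as a factor. Without tendril node 1 or without tendril node 2, when 1 tendril is left, all called features were lower. It was 18670 without inflorescence node 2 replicate 2 (10259 higher) and 11589 without inflorescence node 2 replicate 1 (3048 higher), 4608 without inflorescence node 1 replicate 2, and 80, all lower, with spike-in scaling. Set against the tendrils alone, libraries labelled 06C021V0046 gave 58895 features (32420 higher) and those labelled 06C008V0003 gave 2584 (263 higher). Each of these fits set 2 inflorescence libraries against 2 tendrils, with 1 residual degree of freedom. Their counts therefore cannot be read as a difference between the genotypes.

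**Figure D3:**
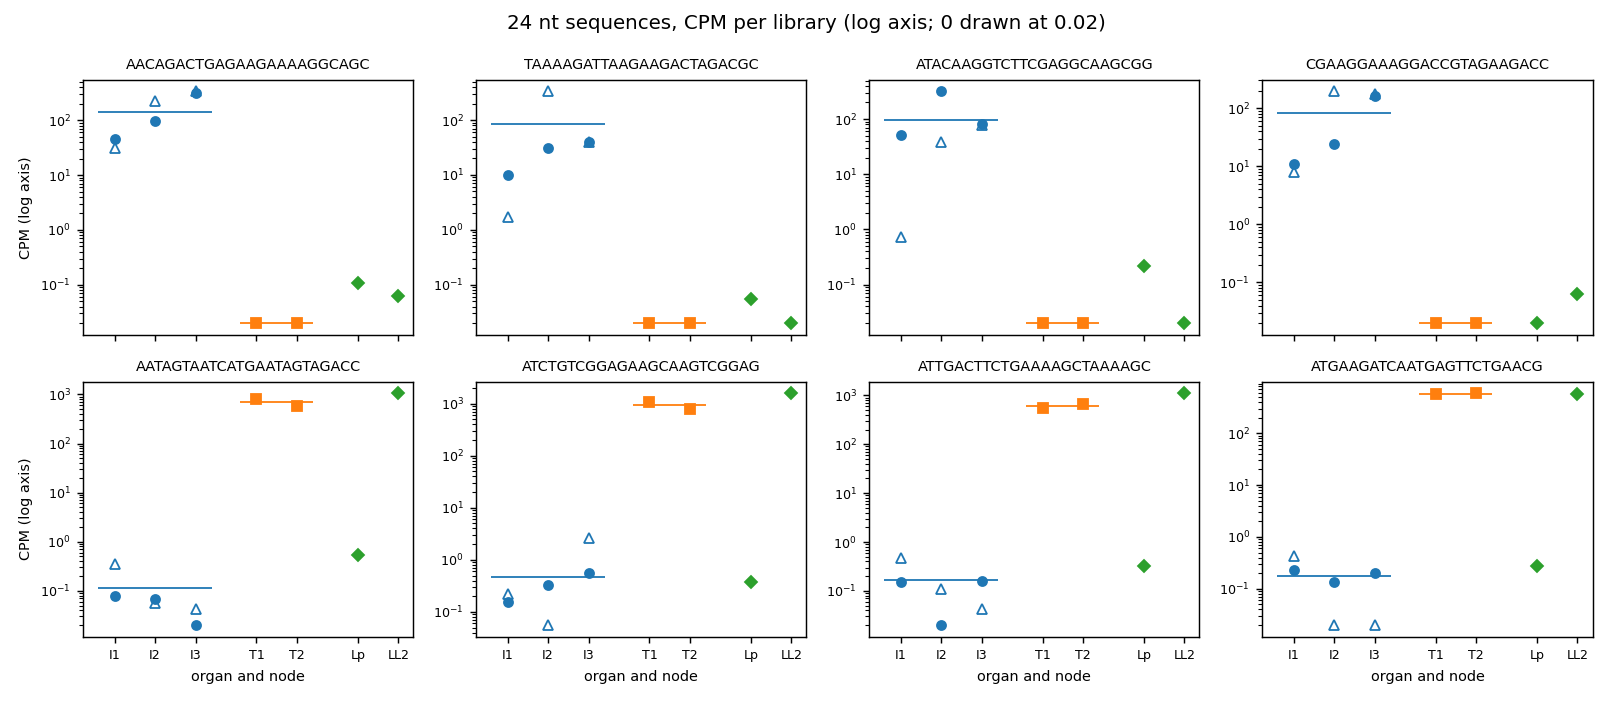
CPM per library (log axis, a level of 0 drawn at 0.02) of the 8 named sequences, with samples and symbols as in the plot of microRNA families. The upper 4 average 81.5 to 144 CPM in inflorescences and have no read in tendril nodes 1 and 2; the lower 4 average 574 to 940 CPM in tendrils.

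A stricter set held sequences of 20 to 24 nt, apart from those on or near the circle of 368 bases, with at least 5 reads in every library of a group and none in any other complete library. Inflorescences had 1343 such sequences, tendrils 120 and leaves 32. Of the inflorescence set, 88.9% were 24 nt long, against 76.0% of all sequences with at least 20 reads. Together they reached 1698 and 1460 CPM in the libraries of node 1, 3372 and 3533 CPM at node 2, and 4330 and 4126 CPM at node 3. Of the 624 that lay in the range covered by the tendril node 3 file, 60 had reads there. The 7 picovine libraries, of 2 genotypes, shared 113 sequences that no L2 library held, and the 3 L2 libraries shared 9116 that no picovine library held, a less strict rule. No test was run on these sets.

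**Figure D4:**
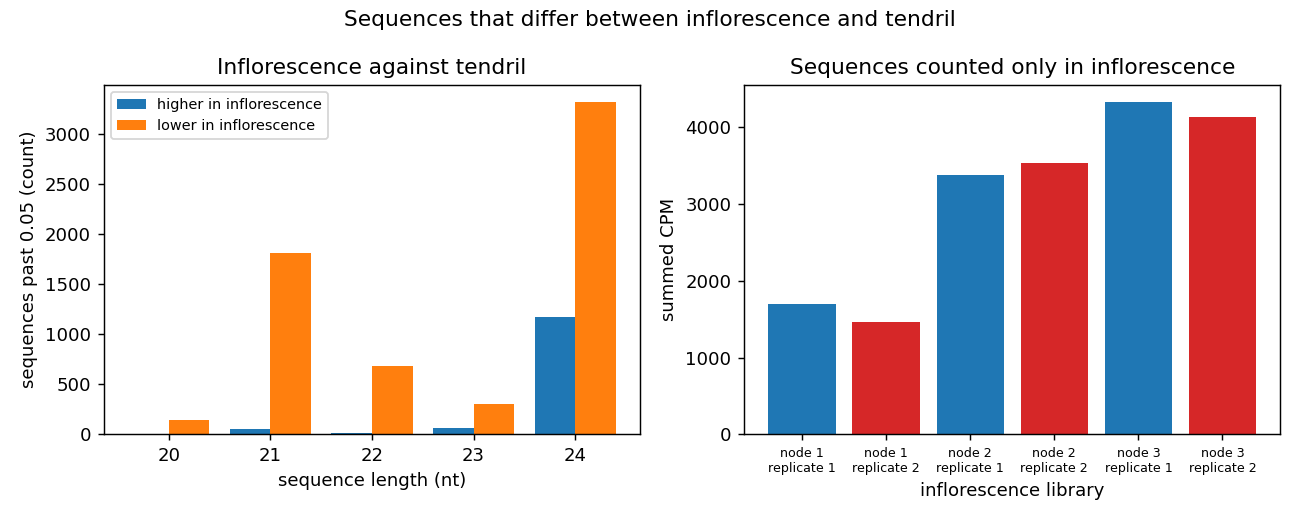
Left, number of sequences (vertical axis) past an adjusted p of 0.05 at each length (nt), higher or lower in inflorescences than in tendrils. Right, summed CPM of the 1343 sequences that, among the complete libraries, were counted only in inflorescences, per library (blue replicate 1, red replicate 2), which lies between 1460 and 4330.

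Whether the change per node differs between inflorescence and tendril was asked with an interaction of organ and node. No feature passed by edgeR (0 of 164159, with 181 at an unadjusted p under 0.05 and 0 by DESeq2). The 181 are less than a share of 0.05 of the features, the share that no change at all would give. The difference in log2 change per node was −2.46 (SE 2.58) for miR172 and 1.15 (SE 2.17) for miR156/miR157, neither beyond its error. The tendril slope rested on nodes 1 and 2 alone. No list of families passed.

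Leaves were compared with the other organ labelled with the same genotype, picovine inflorescence or L2 tendril, although the label of the node 3 inflorescence library is in doubt. The miR167 family had 806 CPM in the picovine leaf and 515 CPM in the L2 leaf (log2 2.97, SE 0.95, adjusted p = 0.316). That fold pools 0.98 against inflorescence with 4.35 against tendril, where miR167 was low. The miR319 family, which targets TCP genes, had 193 and 314 CPM in these leaves (log2 −2.64, SE 1.00, adjusted p = 0.387). The fold of miR156/miR157 was −0.14 (SE 0.90) and that of miR172 −0.84 (SE 1.06). No feature passed by edgeR (0 of 141479, with 12306 at an unadjusted p under 0.05), and DESeq2's Wald test called 1555 (190 higher and 1365 lower in leaf), miR167 among the higher (adjusted p = 0.0299). Without inflorescence node 3 replicate 1, the near-duplicate library labelled 06C021V0046, edgeR called 6245 features (506 higher and 5739 lower in leaf), and miR167 passed (log2 3.02, adjusted p = 0.0471). No list passed fry's test. The nearest were phase and floral timing, with 4 of 4 folds negative, small RNA machinery, with 3 of 3 positive, and auxin signalling, with 4 of 5 positive (adjusted p = 0.0824 each).

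Oligonucleotide standards added to the RNA gave a further scale. Reads of 20 to 24 nt per standard read were 4.53 ± 2.01 on the log2 scale (SD, n = 5) in inflorescences and 2.39 ± 0.35 (SD, n = 2) in tendrils, which did not pass the exact permutation test (p = 0.238). The leaves had 3.96 (picovine) and 3.18 (L2). The mixture of the standards differed between libraries. Std 6 held 85.7% to 96.9% of standard reads in 7 libraries, and 46.2% and 43.8% in the node 3 inflorescence libraries. In inflorescence node 2 replicate 2, Std 2 held 99.2% and Std 6 0.0034%. Without that library the difference was 2.98 on the log2 scale (exact permutation p = 0.0667, the smallest possible with 4 against 2 samples), and with Std 2 alone it was −0.57.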

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

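The node 3 tests, the test of the circular contig as a viroid-like RNA and the separate leaf tests for features higher and lower in inflorescences were chosen after the results were seen. The test of how many features lie on the contig was set after the largest falls had been found on it, but before that share was known. The other tests were set beforehand.

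The miR164 family went in opposite directions from node 1 to node 2 in the genotypes: its log2 level changed by 0.57 in 06C021V0046 and by −2.06 in 06C008V0003. The miR827 family changed by −0.53 in 06C021V0046 and by 1.56 in 06C008V0003. These are 1 pair of libraries each, and the difference between genotypes was not tested. The node 2 library of 06C008V0003 is unusual, with a TMM factor of 1.93 and 99.2% of its standard reads from Std 2. In it, 33 of 37 families were lower than at node 1, so the fall of miR164 there is not particular to miR164, while miR827 rose. The truncated tendril node 3 file, which stayed out of the report's main comparisons, held 155126 reads on the circular contig, above the 0 to 7 reads in picovine libraries.

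The inflorescence node 3 libraries carry the labels of different genotypes but are near duplicates, with a median chi-square of 0.998 per sequence against 5.40 and 18.7 for the pairs of nodes 1 and 2. By this median, nodes 1 and 2 of 06C021V0046 also lay near each other, at 1.47. Over sequences with at least 200 reads the node 3 pair had 1.37 and that pair 12.8. The values argue against the node 3 library labelled 06C021V0046 holding that genotype alone, since it held 94.8% of the 233 sequences that only 06C008V0003 had at nodes 1 and 2, of which the picovine leaf, also labelled 06C021V0046, held 0.43% and the L2 libraries 38.2% to 61.8%, so these sequences are not private to 06C008V0003. What stays open is that 1 RNA or library may have been deposited under both labels, which the median of 0.998 fits, although the noise median is 0.455, so sequencing the same RNA again is nearer than an identical file. The 41.3% of the 567 sequences that only 06C021V0046 had are no sign of a mixture, since the L2 libraries, of another genotype, held 43.9% to 56.8% of them, and they do not exclude one, since the picovine leaf held only 54.7%. No biological explanation was tested.

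Inflorescences and tendrils differed in 7567 features, and organ coincides with genotype. The shallow inflorescence node 2 replicate 2 library is not the source, since the count was 18670 without it, and reads on the circular contig are not the whole of it, since with up to 2 mismatches they cover 25.6% of the features lower in inflorescences. The comparison that includes tendril node 3 in its covered range was set against other splits of its samples. Of 54 splits of the 8 samples that could be fitted, 1 gave as many features, the real one with 12685, and the highest of the others gave 0. Only the real split separates L2 from picovine, and every other split mixes them. The splits show that L2 and picovine samples differ, but cannot exclude chance for an organ difference. Genotype may account for most of the difference: the leaves differ by 75.3% of the organ fold over all called features and by 88.5% over those lower in inflorescences. For the features higher in inflorescences, organ and genotype cannot be told apart, because 94.6% of them are nearly absent from the picovine leaf, and an organ difference stays open for both parts.

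The libraries of L2 shared sequences that assemble into a circle of 368 bases with 61.1% GC, covered on both strands, and the rarer strand held 27.9% of its reads. A candidate explanation is a circular viroid-like RNA from which the plant made small RNAs: of its reads, 38.6% and 40.7% were 21 nt and 38.9% and 38.9% were 24 nt in tendril nodes 1 and 2, against 32.9% and 48.2% in the L2 leaf and 30.2% and 49.4% in the covered range of tendril node 3. A tandem repeat of the grapevine genome would also close into a circle at an overlap of 14 bases, so the origin stays open without a genome or a reference of viroids. No species is assigned, and a genotype difference between L2 and picovine was not tested apart from it.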

How the results depend on the processing

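Alternatives for the truncated, duplicate and contig sequences and for the 18S fragment were chosen after seeing the data, the others before. DESeq2's Wald test called 37, 26 and 30 features for nodes 2 against 1, 3 against 1 and 3 against 2, and 1555 for leaf. The replicate block called 1 feature for node 2 against 1, 2215 for node 3 against 1, and 1 there without the node 3 library labelled 06C021V0046. It changed no other count or list, and within nodes 1 and 2 alone it called 0. All other alternatives of the node comparisons, and all of the slope, called 0. For leaf the count ranged from 0 to 6245 on leaving out 1 library (the highest without inflorescence node 3 replicate 1).

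For inflorescence against tendril, the count ranged on leaving out 1 library from 155 (without tendril node 1) to 18670 (without inflorescence node 2 replicate 2). When 1 tendril is left out, the lone one is assumed to vary like the other group. The count was 80 with spike-in scaling, 11536 with no filter, 58895 and 2584 with only 06C021V0046 and only 06C008V0003, 12685 with tendril node 3 in the covered range and 3455 without it there, and 5031 without the contig. It was 0 with genotype as a factor, with or without node 3 inflorescences. The fits of each genotype alone left 1 residual degree of freedom. The share lower, 82.8%, depended on the test: it was 51.2% of 11197 with DESeq2's Wald test, 47.0% with tendril node 3 in the covered range (74.3% without it there) and all 80 with spike-in scaling. Spike-in scaling moved the median of all features by 2.33 (log2), and DESeq2's size factors moved it by −0.13. For nodes 2 against 1, 3 against 1 and 3 against 2, spike-in scaling moved it by −1.38, 1.01 and 2.78 and the size factors by 0.11, −0.41 and −0.56. Size factors moved it by −0.18 for leaf, and spike-in scaling by −0.16 for the slope. List tests past 0.05 were 3, and 0 with spike-in scaling.

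The 24 nt difference was 12.9 points with tendril node 3 in the covered range and 12.7 without the 18S fragment, both past 0.05. The 21 nt difference was −5.77 over 20 to 24 nt, −2.77 over unique sequences and −3.84 with tendril node 3, all past 0.05. Reads per standard read turned to −0.57 with Std 2 alone.

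Reversed log2 folds, none past 0.05, were as follows. Inflorescence against tendril, spike-in scaling: miR390 0.32, miR172 1.26, tasiARF 0.83. That scaling raised the median fold of all features, as given above, so these turns are not particular to these families. miR172 was 1.39 from its most abundant sequence and 0.56 with genotype as a factor without node 3. ATCTGTCGGAGAAGCAAGTCGGAG was 0.59 with genotype as a factor, 0.16 without node 3. Node 3 against 2: miR172 0.024 (identical reads) and 0.12 (replicate block without the library labelled 06C021V0046), miR156/miR157 1.56 (spike-in scaling) and 0.28 (that block). Leaf: miR172 3.69 (identical reads), miR156/miR157 0.16 (spike-in scaling) and 0.91 (against tendril). Leaving out 1 library gave ranges across 0 for miR172 (−6.38 to 0.10 for node 2 against 1, −4.29 to 1.10 for 3 against 2) and miR156/miR157 (−0.0025 to 1.91 for 3 against 1, −1.32 to 0.56 for 3 against 2, −1.36 to 0.96 for leaf). Apart from the shift of scale under spike-in scaling, the cause was not tested. Of 395 alternatives for named families, 363 kept direction and side of the threshold, 18 reversed, 5 lost the call (miR3627-like) and 9 gained one; of 172 for named sequences, 138 did, and 32 lost the call.

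A match to a genome was not run, as none was used here, and the slope cannot be fitted without a tendril library. Leaf results rest on 1 library per genotype.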

Other observations

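Families differed widely between the picovine genotypes at nodes 1 and 2. The miR535 family had 22707 and 28027 CPM in the libraries of 06C021V0046 against 957 and 378 CPM in those of 06C008V0003, and 15861 CPM in the leaf of 06C021V0046. The miR164 family, which targets NAC genes of organ boundaries, had 2833 and 4206 CPM against 71.4 and 16.8 CPM. Both node 3 libraries had low levels, 360 and 327 CPM of miR535 and 110 and 95.7 CPM of miR164. Genotype and replicate coincide here, so these are values of single libraries and were not tested.

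The first base of the reads followed length. Of 21 nt reads, 46.6% to 65.6% began with U in the 10 complete libraries, and of 24 nt reads 39.0% to 43.6% began with A. By mean level in each organ, the most abundant family was miR159, with 25511 ± 20048 CPM (SD, n = 5) in inflorescences, 32558 ± 7773 CPM (SD, n = 2) in tendrils and 22260 ± 2094 CPM (SD, n = 2) in leaves. In the node 1 and 2 libraries of 06C021V0046, miR159 had 14781 and 11242 CPM, below miR535. The copper-related families miR397, miR398 and miR408 had 431, 81.4 and 177 CPM in the picovine leaf and 97.6, 5.22 and 10.6 CPM in the L2 leaf, with 1 library each.

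One hypothesis, with its test set before its result was seen, was that the opposite courses of miR156/miR157 and miR172 from node 1 to node 2 may be chance in a pair of genotypes. Of 37 families, 73.0% changed in the same direction in both genotypes (two-sided exact binomial p = 0.00763 against 50%). The bound of 50% was wrong, because 27 and 33 families were lower at node 2 in the genotypes, which alone gives 68.0%. Given those totals, Fisher's exact test gave p = 0.291. Families are not independent replicates, and the hypothesis stays open.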
